A study of Mus musculus with 4 samples.

How the data were processed

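Whole-genome bisulfite sequencing was done on DNA from the somatosensory cortex of mice aged 2.5 months, in 2 libraries of the Nsd1 conditional knockout (cKO) and 2 control libraries. Per the labels, DNA was extracted with CTAB, sheared, treated with bisulfite and amplified by PCR into Illumina libraries. The submitters' processing notes name CASAVA, Bowtie2 and the genome build mm10, without versions or roles. The caller of the regions, its thresholds and the way replicates entered it are not given in the sources used here, nor is the share of cytosines converted. The labels number the replicates and do not say whether they come from separate animals.

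The authors' deposited table holds 101350 regions of differential methylation between cKO and control, with 0 repeated regions. Each region has a mean methylation level per group, deposited as a fraction from 0 to 1 and printed here as a percent. The deposited difference is cKO minus control, which matched the levels in all 101350 regions within 1e-09. The deposited area statistic is a score with no fixed range, summed over the cytosines of a region, and was used only to rank or filter regions. The number of cytosines, the length and the context (CG, CHG or CHH) are also the authors'. The shortest region has 51 bp and the fewest cytosines are 4. The smallest absolute difference in CHG and CHH is 2.00 points. Because the table lists called regions only, it gives neither levels in the rest of the genome nor the genome-wide mean. It holds no values per library and no coverage, so depth is unknown and no spread, permutation test over mice or coverage filter could be had, and bisulfite errors or differences in depth between groups would enter the group means unseen. Intervals over regions cover counting only (95%, exact Clopper-Pearson for shares and by normal approximation for odds ratios on the X).

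Gene positions came from RefSeq on GRCm38.p6, the assembly of mm10. Genes listed in the first 3 Mb of an autosome or the X were left out, because those sequences are gaps and the entries lie on scaffolds. This left 49640 genes, 21792 of them protein-coding. A region belonged to a gene when they shared at least 1 bp; in rankings of regions, a protein-coding gene came before others and a shorter before a longer one. The design had named the deposited gene annotation as the first choice, and overlap with the gene body took its place because the table pairs regions with no gene. Strand, exons, promoters, CpG islands and repeats were not analysed here. Placement was compared with 1000 sets of random regions of the same length on the same chromosome, between its first and last region. Direction inside against outside genes was compared with Fisher exact tests, adjusted by Benjamini-Hochberg. Directions were permuted over CHH regions 1000 times for genes with at least 10 of them.

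The 24 gene lists were written before the data were examined, and 692 of their 693 genes matched. For each list, context (CG, CHH) and direction, the number of members with a region was placed among 10000 random lists of the same size matched on gene length in 20 bins, with a two-sided p (the smallest possible being 0.0002), adjusted by Benjamini-Hochberg over all 92 tests against a background of 21786 genes. The procedure was tested on simulated data with 8596 regions dropped on genes by length, for CHH regions higher in cKO. These runs drew fewer random lists and adjusted over the lists of that context and direction alone, not over all 92 tests. They did not cover CG regions or CHH regions lower in cKO. A list with its rate raised 30 times, a large effect, was found in 20 of 20 runs and one lowered to 0.2 in 15, and 0 of 400 tests of other lists passed. The first bound for the lowered list was 18 runs, and it was set to 10 after the 15 were seen, so fewer members than at random are found less surely. The clustered protocadherins passed in all 20 runs with no planted effect, since 1 region falls in many of their overlapping models, so that list was described without a test. The direction of each list's regions was set against that of other genes with Fisher exact tests (two-sided, adjusted over 46). As regions of 1 gene are not independent, the same test was run with 1 vote per gene, an alternative added after the data were seen, as was the filter on CHH differences above the mitochondrial median.

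Genes were named by a rule fixed at the same time as the lists. It took Nsd1, then per direction the 8 CG regions with the largest absolute area statistic in a gene (1 per gene), the 4 with the largest difference over at least 10 CpGs, and the 5 genes with the most regions. From each list it took up to 4 members with the largest area statistic in CG. Predicted gene models were passed over. Results for some genes that the rule takes are not reported here. The same ranking in CHH, the genes first by density, the region near Scpep1 and Sox6 were chosen after their values were seen. Alternatives tried were absolute differences of at least 0.2 and 0.3, at least 5 and 10 cytosines, lengths of at least 100 and 200 bp, the stronger part of the regions split at the median area statistic, neighbours under 1 kb apart merged, autosomes alone, genes widened by 2 kb on both sides (planned for the upstream side, but strand was not used), lists not matched on length, and regions per 100 kb. In those alternatives 200 random sets of regions were drawn, and shares and medians were given over at least 20 regions. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for figures.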

Results

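DNA methylation was measured by whole-genome bisulfite sequencing in the somatosensory cortex of mice aged 2.5 months. Bisulfite converts unmethylated cytosines, so that the cytosines still read as such give the methylation level of a site. The 2 groups were a conditional knockout of Nsd1 under the Nex driver (cKO, n = 2 libraries) and a control labelled Nsd1fl/+ (n = 2 libraries). NSD1 is a histone methyltransferase that places methyl groups on lysine 36 of histone H3, and the Nex (Neurod6) driver acts in excitatory neurons of the cortex. The comparison asks where DNA methylation differs when NSD1 is removed from these neurons. The authors' deposited table lists 101350 differentially methylated regions in mm10, each with the mean level of both groups, in the contexts CG, CHG and CHH, where H stands for A, C or T. It gives group means only, so no spread between libraries can be set beside any difference, and the depth is unknown.

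Inside Nsd1 itself (chromosome 13, 55209782 to 55318325), the authors' deposited table lists methylation outside the CG context that was higher in cKO. The 5 CHH regions lie within 3.63 kb, from 55245173 to 55248799, and hold 557 cytosines. Their means ranged from 4.77% to 7.90% in cKO and from 0.405% to 0.834% in control. Among all 8596 CHH regions higher in cKO, the first of these had the second largest area statistic. Of the windows of 4 kb that start at such a region, 1 outside Nsd1 held as many. The 2 CHG regions in the same stretch reached 9.43% and 10.7% in cKO against 0.475% and 0.380% in control. A CG region at the start of the gene (55210007 to 55210165, 31 CpGs) went the other way, with 29.8% in cKO and 50.4% in control. Exon positions were not analysed here, and these levels do not show how far the gene was deleted in either library.

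**Figure D1:**
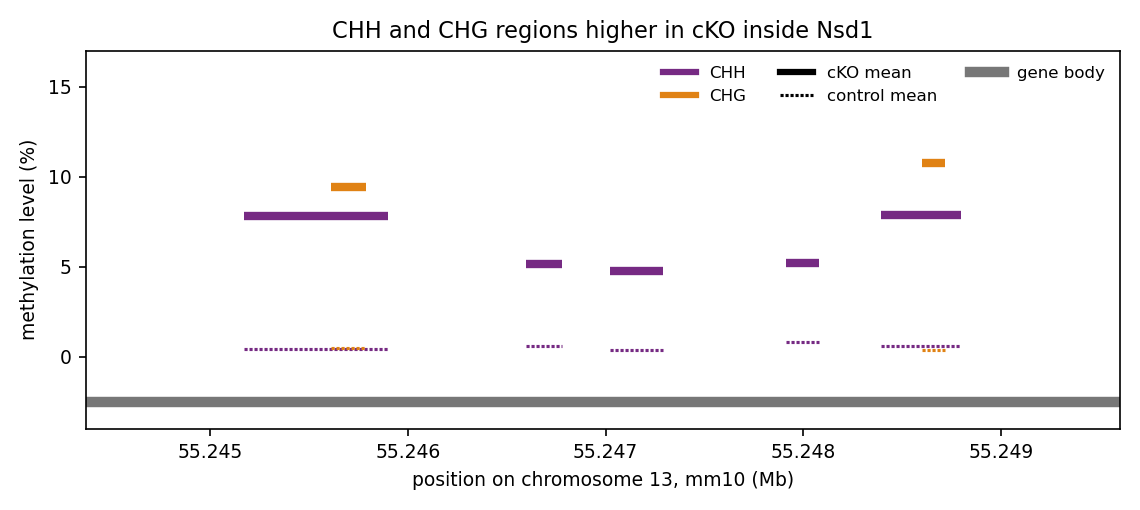
Mean methylation level (%, vertical axis) of the CHH and CHG regions inside Nsd1 along chromosome 13 (mm10, Mb), with thick lines for the cKO mean, dotted lines for the control mean and a grey bar for the gene body. The 5 CHH regions sit between 4.77% and 7.90% in cKO and below 1% in control.

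In the CG context, methylation was lower in cKO at nearly all listed regions. Of 47123 CG regions in the authors' deposited table, 44497 were lower in cKO (94.4%, 95% exact binomial interval 94.2% to 94.6%) and 2626 were higher. In the regions that were lower, the median level was 76.0% in control and 42.4% in cKO, with a median difference of -31.2 points (quartiles -35.8 and -26.7). In the regions that were higher, the median level was 51.1% in control and 78.0% in cKO, with a median difference of 24.2 points (quartiles 20.4 and 28.0). The regions lower in cKO covered 8.05 Mb and those higher 0.323 Mb. The interval covers the counting of regions only, since neighbouring regions share cells and reads and are not replicates.

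**Figure D2:**
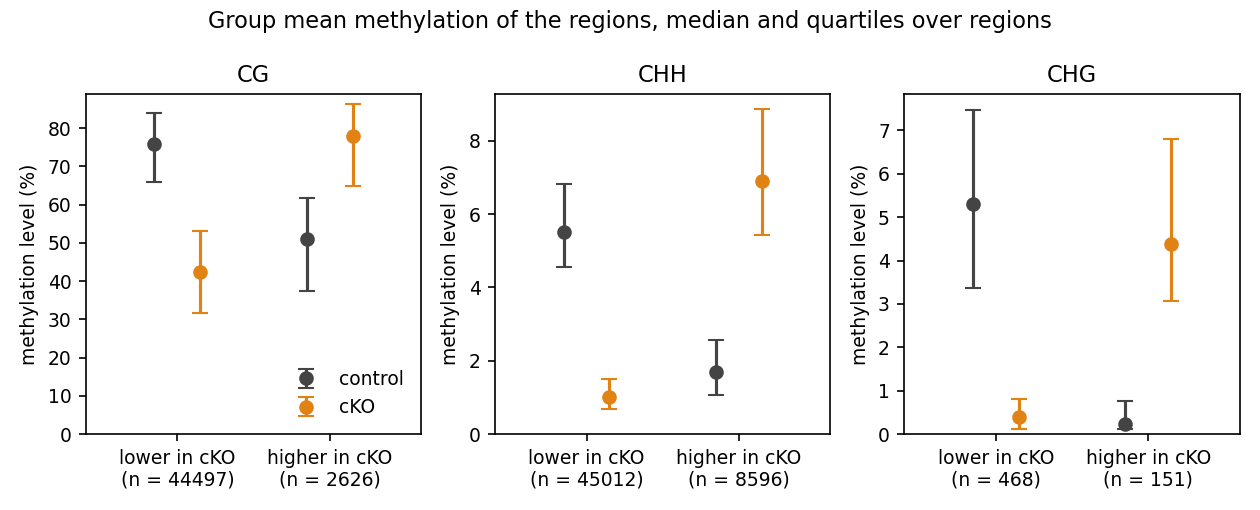
Methylation level (%, vertical axis) of the regions lower and higher in cKO in each context, with points for the median over regions of the group mean and bars for the quartiles (control in grey, cKO in orange, n the number of regions). CG regions lower in cKO went from a median of 76.0% in control to 42.4%, and CHH regions lower in cKO from 5.52% to 1.01%.

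In the authors' deposited table the strongest CG region lower in cKO inside a named gene lay in Pi16 (chromosome 17, 29322175 to 29323204, 110 CpGs), at 42.2% in cKO and 77.4% in control. Hic1, a transcriptional repressor, went from 47.1% in control to 19.5%, and Jak3, a cytokine receptor kinase, from 72.0% to 33.5%. Prdm16, a zinc finger transcription factor, went from 78.9% to 35.1% (chromosome 4, 154594216 to 154595108, 70 CpGs). Lca5l (25.5% to 7.57%), Mpst (44.2% to 24.4%), Zmiz1os1 (47.5% to 14.9%) and Tmem28 on the X (43.4% to 20.3%) completed the first 8. Among regions inside named genes, the largest loss over at least 10 CpGs was in Gli3, a transcription factor of the Hedgehog pathway, at 79.2% in control and 21.2% in cKO (chromosome 13, 15602263 to 15602523). Ccdc192 (85.7% to 30.2%), Pxylp1 (81.9% to 27.4%) and Ltbp2 (83.8% in control, a difference of -53.8 points) followed. Outside genes, the strongest region of all (chromosome 11, 88895190 to 88896507, 167 CpGs) went from 92.9% to 35.9%, at 27.5 kb from Scpep1.

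In the authors' deposited table the strongest CG region higher in cKO lay in Gprin1, which acts in neurite outgrowth (chromosome 13, 54737569 to 54738462, 231 CpGs), at 23.4% in cKO and 9.81% in control. Cacna1a, the pore subunit of P/Q-type calcium channels, held 24.9% in cKO and 10.8% in control over 220 CpGs (chromosome 8, 84558981 to 84559704). Fbxo41 was at 41.0% in cKO against 18.4%, and Dtx1, a regulator of Notch signalling, at 54.0% against 27.3%. Tmem267 (75.9% against 57.4%), Zfp316 (51.4% against 31.3%), Sh2b3 (39.6% against 23.0%) and Dact3 (69.7% against 50.1%) completed the first 8. Among regions inside named genes, the largest gains over at least 10 CpGs were in Trmt61a, a tRNA methyltransferase (90.1% in cKO, 42.5% in control), Gtdc1 (86.8%, 43.9%), Dok5 (75.1%, 32.2%) and Sh3kbp1 on the X (66.4%, 24.0%).

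Methylation outside CG moved in both directions, with more regions lower than higher in cKO. Of 53608 CHH regions in the authors' deposited table, 45012 were lower (84.0%, 95% exact binomial interval 83.7% to 84.3%), with a median level of 5.52% in control and 1.01% in cKO. The 8596 CHH regions higher in cKO had a median of 1.69% in control and 6.90% in cKO. Of 619 CHG regions, 468 were lower (5.31% in control, 0.398% in cKO) and 151 were higher (0.225% in control, 4.38% in cKO). The strongest CHH loss in a named gene was in Prdm16 (chromosome 4, 154596204 to 154597292, 390 cytosines), from 8.02% to 1.81%, next to its strongest CG loss. The strongest CHH gain was in Det1 (chromosome 7, 78831628 to 78832639, 382 cytosines), from 1.78% to 7.04%. All 17 regions on mitochondrial DNA were lower in cKO, and the 4 CHH regions there, over 3967 cytosines, averaged 6.52% in control and 0.510% in cKO. Of the CHH regions, 10054 differed by more than the mitochondrial median of 5.87 points, and 71.9% of these were lower in cKO, a filter added after the data were seen.

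Gains in cKO lay mostly inside protein-coding genes, whereas losses lay there less often than random regions. Of the regions in the authors' deposited table, 91.2% of the CG regions higher in cKO and 91.4% of the CHH regions higher in cKO overlapped a protein-coding gene. Random regions of the same lengths on the same chromosomes did so in 41.4% and 41.2%. They were not matched on the density of cytosines or on whether a region could have been called there. The CG regions lower in cKO overlapped such a gene in 31.0% and the CHH regions lower in cKO in 24.9%, against 41.2% of random regions for both. The CHG regions split alike, with 70.2% of those higher and 28.0% of those lower inside protein-coding genes. Each of these shares lay outside the whole range of 1000 random sets (permutation of positions, two-sided p = 0.002, the smallest they can give). Inside protein-coding genes 41.2% of CHH regions were higher in cKO and outside them 2.14%, an odds ratio of 32.1. For CG regions the shares were 14.8% and 0.744%, an odds ratio of 23.1. For CHG regions they were 44.9% and 11.8%, an odds ratio of 6.07 (Fisher exact test, two-sided, adjusted p = 5.19e-20). These tests describe the listed regions, not the mice, and promoters, exons and CpG islands were not analysed here.

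**Figure D3:**
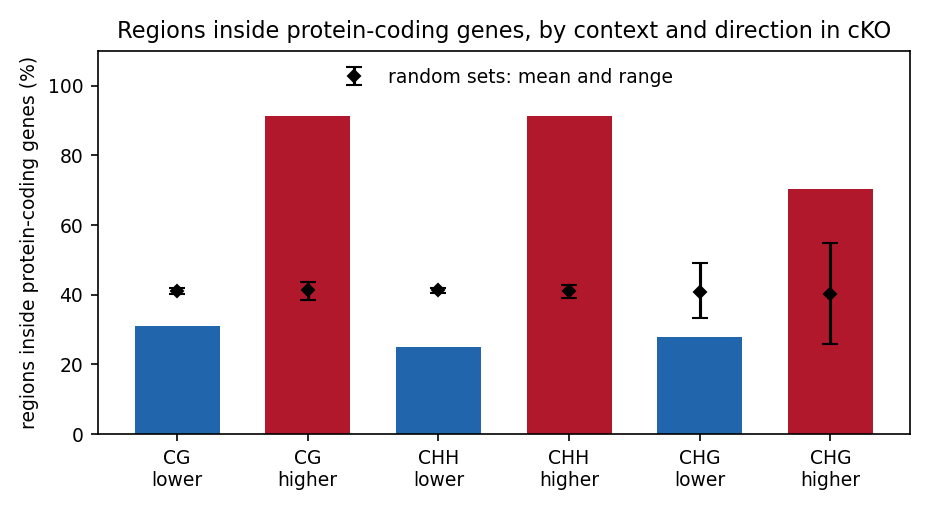
Share of regions that overlap a protein-coding gene (%, vertical axis) by context and direction in cKO, with blue bars for regions lower and red bars for regions higher in cKO, and black diamonds with bars for the mean and range of 1000 random sets. Regions higher in cKO stand above the random sets in every context (91.2%, 91.4% and 70.2%) and regions lower in cKO below them (31.0%, 24.9% and 28.0%).

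Many genes carried regions of mainly 1 direction. In the authors' deposited table the genes with the most CG regions lower in cKO were Prdm16 with 67, Lrmda with 63, Tenm3 with 61, Rad51b with 58 and Wwox with 57. Prdm16, Lrmda, Rad51b and Wwox held 0 CG regions higher in cKO, and Tenm3 held 3. The genes with the most CG regions higher in cKO were Klhl29 with 14, Celf2 and the transcription factor Zeb2 with 13 each, and Atxn1 and Mtcl1 with 11 each. In the CHH context, Rbms3 had 103 regions lower in cKO, Prdm16 83, Wwox 82, Lrmda 73 and Alk 72. The CHH regions higher in cKO were most frequent in Nrxn3, a presynaptic adhesion molecule, with 27, then Camta1 with 21, Syne1 with 20, and Tenm2 and the splicing factor Rbfox1 with 19 each. Of 338 protein-coding genes with at least 10 CHH regions, 215 had at least 90% of them lower and 76 at least 90% higher. When directions were permuted over regions 1000 times, these numbers averaged 4.93 and 0.21 and never exceeded 13 and 2. The permutation treats regions of a gene as independent, which they are not. It therefore cannot tell a direction shared by the gene from likeness between neighbouring regions. Ranking by regions per 100 kb among genes with at least 5 put other genes first, chosen after their values were seen, led by Tbx1 for CG losses (72.2 per 100 kb), Brpf3 for CG gains (13.3), Il21 for CHH losses (60.7) and Det1 for CHH gains (23.1).

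Transcription factors of other lineages and interneuron markers carried CHH losses more often than random lists. Of 71 developmental transcription factors of other lineages, 27 carried a CHH region lower in cKO, against a mean of 8.53 in random lists matched on gene length, a permutation of genes within length bins (adjusted p = 0.0092). 1 member carried a CHH region higher in cKO, where random lists had a mean of 6.82 (adjusted permutation p = 0.0396), a call that held under 2 of 5 alternative settings (highest adjusted p = 0.350). Their CHH regions were 131 lower and 1 higher, and their CG regions 68 lower and 0 higher, in 19 members (10.4 at random, adjusted permutation p = 0.0478, a call that held under 2 of 6 alternative settings, with a highest adjusted p of 0.206). Examples are Tbx1 (52.0% to 22.4% CG methylation over 84 CpGs), Twist2 (42.3% to 15.5%), Pax2 (84.8% to 43.6%) and Zic5 (50.1% to 22.0%). Of 28 interneuron markers, 13 carried a CHH region lower in cKO against 4.50 at random (adjusted permutation p = 0.0092), with 130 CHH regions lower and 3 higher. The transcription factor Sox6 alone had 60 of them. A CG region lower in cKO was carried by 10 of these markers, which did not pass the list test (5.67 at random, adjusted permutation p = 0.176), with levels of 56.0% and 31.2% in Prox1, 74.2% and 41.4% in Reln and 74.0% and 40.4% in Adarb2 in control and cKO. Counted as 1 vote per gene, chosen after the data were seen, 27 of 28 genes of the first list and 13 of 14 of the second were mostly lower in CHH (Fisher exact test, two-sided, adjusted p = 9.46e-06 and 0.0167). The call for CHH losses held under 5 of 5 alternative settings for the first list (adjusted p by permutation or, without length matching, by Fisher exact test, from 2.36e-05 to 0.0184) and under 4 of 5 for the second. It ended for interneuron markers when only CHH differences above the mitochondrial median were kept (adjusted permutation p = 0.184, from 0.000601 by Fisher exact test to 0.184 over the alternatives), at a ratio to random of 2.86 against 2.89 before.

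For markers of non-neuronal cells, 5 of 8 tests of losses passed, and in each of the 4 lists at least 1 did. Of 16 microglia markers, 8 carried a CHH region lower in cKO (1.81 at random, adjusted permutation p = 0.0184) and 7 a CG region lower (2.16 at random, adjusted p = 0.0396), among them Spi1, a myeloid transcription factor (37.4% to 18.5%), and Sall1 (65.4% to 44.4%). Of 16 endothelial and mural markers, 9 carried a CHH region lower in cKO (3.13 at random, adjusted permutation p = 0.0184) and 8 a CG region lower, which did not pass (3.82 at random, adjusted p = 0.113), with CG levels in Pdgfrb of 70.6% in control and 37.3% in cKO and in Kdr of 28.0% and 7.48%. Of 18 oligodendrocyte lineage markers, 9 carried a CG region lower (3.38 at random, adjusted permutation p = 0.0299), including Mbp, a myelin protein (70.6% to 40.6%), and of 16 astrocyte markers 8 did (3.16 at random, adjusted p = 0.0447), including Gfap (40.3% to 19.9%) and Slc1a3 (64.6% to 26.2%). The CHH losses of these 2 lists, in 6 and 7 members, did not pass (2.73 and 2.56 at random, adjusted permutation p = 0.232 and 0.053). The CG regions were 13 lower and 0 higher for microglia and 29 and 1 for endothelial and mural markers. They were 20 and 3 for oligodendrocyte lineage and 17 and 0 for astrocyte markers. None of these splits passed the Fisher exact test of direction against other genes, where 14.8% were higher. In CHH that test passed by region for all but astrocyte markers, and with 1 vote per gene for endothelial and mural markers alone. When only CHH differences above the mitochondrial median were kept, the microglia and endothelial calls in CHH ended, at ratios to random of 4.87 (4.43 before) and 1.61 (2.87 before), and each held under the other 4 settings (adjusted p from 0.00368 to 0.406 by permutation, and from 0.000926 by Fisher exact test to 1). The CG calls held under 5 of 6 alternative settings for astrocyte and 4 of 6 for oligodendrocyte lineage markers (highest adjusted permutation p = 0.132 and 0.179) and under 2 of 6 for microglia markers (highest adjusted p = 1).

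In synaptic adhesion and voltage-gated channel genes, CHH regions were higher in cKO more often than in other genes. The CHH regions of synaptic adhesion genes were 142 higher and 56 lower in cKO, or 71.7% higher against 40.9% in other genes (Fisher exact test, two-sided, adjusted p = 5.23e-17), and 24 of 28 genes were mostly higher (adjusted p = 0.00217). The number of members with such a region, 27 of 46 against 19.9 at random, did not pass the list test (adjusted permutation p = 0.091). The CG regions of this list were mostly losses, with 125 lower and 24 higher, or 16.1% higher against 14.8% in other genes. CG gains included Nrxn2 (26.1% in control, 42.1% in cKO) and Ptprs (9.69%, 26.7%), while Cntnap4 went from 86.9% to 44.1%. Of voltage-gated channel genes, 24 of 30 were mostly higher in CHH (Fisher exact test, adjusted p = 0.0114), with 84 regions higher and 78 lower. By region, 51.9% were higher against 41.1% in other genes. The number of members with a CHH region higher, 27 of 42 against 21.2 at random, did not pass the list test (adjusted permutation p = 0.199). These tests of direction, unlike the list test, were not matched on gene length. The CG regions of the channel genes were 64 lower and 33 higher. Besides Cacna1a, Hcn2, a pacemaker channel, gained CG methylation (54.4% to 72.7%), and Kcnd3 lost it (65.4% to 23.1%). Of 30 activity-regulated genes, 5 carried a CG region higher in cKO and 0 a lower one (1.12 at random for higher, adjusted permutation p = 0.0483). They included Egr3 (17.5% to 37.0%), Nr4a1 (38.7% to 64.6%), Nr4a3 (23.3% to 41.1%) and Npas4 (24.4% to 39.8%). That call held under 1 of 6 alternative settings (adjusted permutation p from 0.0158 to 1), and 0 members had a region left at an absolute difference of at least 0.3.

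Deep layer, area patterning, axon guidance and imprinted genes carried CG regions more often than random lists. Of 23 deep layer identity genes 16 had a CG region lower in cKO (8.92 at random, adjusted permutation p = 0.0184), among them Sox5 (66.6% to 27.9%) and Fezf2 (29.6% to 12.5%), and the strongest in Nxph4 was a loss too (43.0% to 20.8%), while that in Ldb2 was a gain from 35.5%. Of 30 genes of cortical area patterning, 15 had a lower CG region (8.13 at random, adjusted permutation p = 0.0368) and 9 a higher one (3.33 at random, adjusted p = 0.0396). In this list Fgf17 went from 62.4% to 28.0%, Pax6 from 34.8% to 17.4% and Tshz2 from 75.4% to 38.7%. Of 49 axon guidance genes 31 had a lower CG region (21.5 at random, adjusted permutation p = 0.0396), including Ntn1 (86.3% to 44.4%), Slit3 (68.1% to 29.3%) and Unc5b (72.9% to 33.6%). Of 40 imprinted genes 17 had a lower CG region (9.06 at random, adjusted permutation p = 0.0299), including Peg3 (60.7% to 32.9%), Cdkn1c (40.7% to 20.2%) and Kcnq1 (61.7% to 22.8%). A higher CG region was carried by 12 (1 to 8 in 95% of random lists, adjusted permutation p = 0.0184), including Gnas (25.7% to 39.2%). These 12 members hold only 12 distinct regions, 3 of them in Gnas, so some members were counted through the same region. The p for imprinted gains may therefore be too small. Under 6 alternative settings the calls for CG losses held in 5 for the deep layer list, in 4 for area patterning, in 4 for axon guidance and in 1 for imprinted genes (highest adjusted permutation p = 0.676, 0.163, 0.0719 and 0.719). The calls for CG gains held in 3 for area patterning and in 4 for imprinted genes (highest adjusted permutation p = 1 and 0.742).

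The other lists did not pass the test against matched random lists after adjustment over all 92 tests, of which 16 passed. At an absolute difference of at least 0.2, and likewise 0.3, 3 of the 16 passed when adjusted over the 46 CG tests that kept regions, a restriction made after the values were seen, and 0 passed over all 92. The numbers of settings given for each list use the former. Of 46 Fisher exact tests of direction, 23 passed by region and 7 also with 1 vote per gene. Upper layer identity genes had 7 of 20 members with a CG gain (3.22 at random, adjusted permutation p = 0.176), among them Cux2 (8.65% to 22.5%) and Rorb (73.6% to 94.7%). A CG loss was carried by 9 members (7.32 at random, adjusted permutation p = 0.871), among them Pou3f2 (48.0% to 13.7%). By region the list had 60 CG losses and 13 gains. Of 13 excitatory neuron markers, 2 carried a CHH region higher in cKO (2.58 at random) and 0 a lower one (2.43 at random). The 2 with a gain were Neurod1 (3.13% to 10.9%) and Sv2b (0.709% to 3.80%), both named after their values were seen. GABA receptors had 13 CG regions higher and 8 lower, with 10 of the gains in Gabbr2 (54.1% to 83.4% in the strongest). Glutamate receptors had 57 CHH regions higher and 32 lower, but 11 CG regions higher and 45 lower. Grin1 gained CG methylation (10.2% to 25.9%), while Grik4 lost it (50.4% to 21.4%). Of 14 enzymes of H3K36 methylation, 5 carried a CHH region higher in cKO, near the 4.85 at random. A lower one was carried by 0 (3.90 at random, adjusted permutation p = 0.0911). The list includes Nsd1 itself, which held 5 of its 10 CHH regions higher in cKO. Cadherins had 143 CG regions lower and 5 higher, with 48 in Cdh13 and 46 in Cdh4. Polycomb and H3K27 enzymes had 5 CG regions in each direction, with a gain in Kdm6b (33.0% to 54.4%). Enzymes and readers of DNA methylation had 10 CHH regions higher and 2 lower, and their CG regions included a gain in Mbd2 (9.26% to 20.3%). Hox genes had 8 CHH regions lower and 0 higher, with a CG loss in Hoxc9 (43.1% to 15.8%). Of 18 housekeeping genes, 1 carried a CG region, Hprt on the X (25.6% to 10.8%). Clustered protocadherins such as Pcdhga1 shared 1 CG region of only 4 CpGs, higher in cKO (21.8% to 65.2%). The list also held 1 CHH region, lower in cKO, and was not tested because its gene models overlap.

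The X chromosome carried far fewer regions than the autosomes. In the authors' deposited table the X had 1.46 CG regions lower in cKO per Mb against 18.5 on the autosomes, where single chromosomes ranged from 15.4 to 21.6. For CG regions higher in cKO the X had 0.211 per Mb against 1.08. CHH regions showed the same order, with 2.67 against 18.6 per Mb for losses and 1.02 against 3.52 for gains. The share of regions lower in cKO was smaller on the X, with 87.4% against 94.5% in CG (Fisher exact test, two-sided, p = 8.21e-06) and 72.4% against 84.1% in CHH (p = 3.19e-13). Single autosomes ranged from 93.3% to 96.1% in CG and from 80.3% to 87.3% in CHH. The Fisher tests count regions as independent, which neighbours are not. At an absolute difference of at least 0.2 the CG shares were 93.0% and 95.5% (odds ratio 0.630, Fisher exact p = 0.0789), and at 0.3 they were 96.1% and 98.4% (odds ratio 0.411 on 129 X regions, p = 0.0618), against an odds ratio of 0.406 on 278 X regions in the full table. The Y carried 6 regions. The sex of the mice is not given in the labels, and CpG numbers per chromosome were not analysed here.

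**Figure D4:**
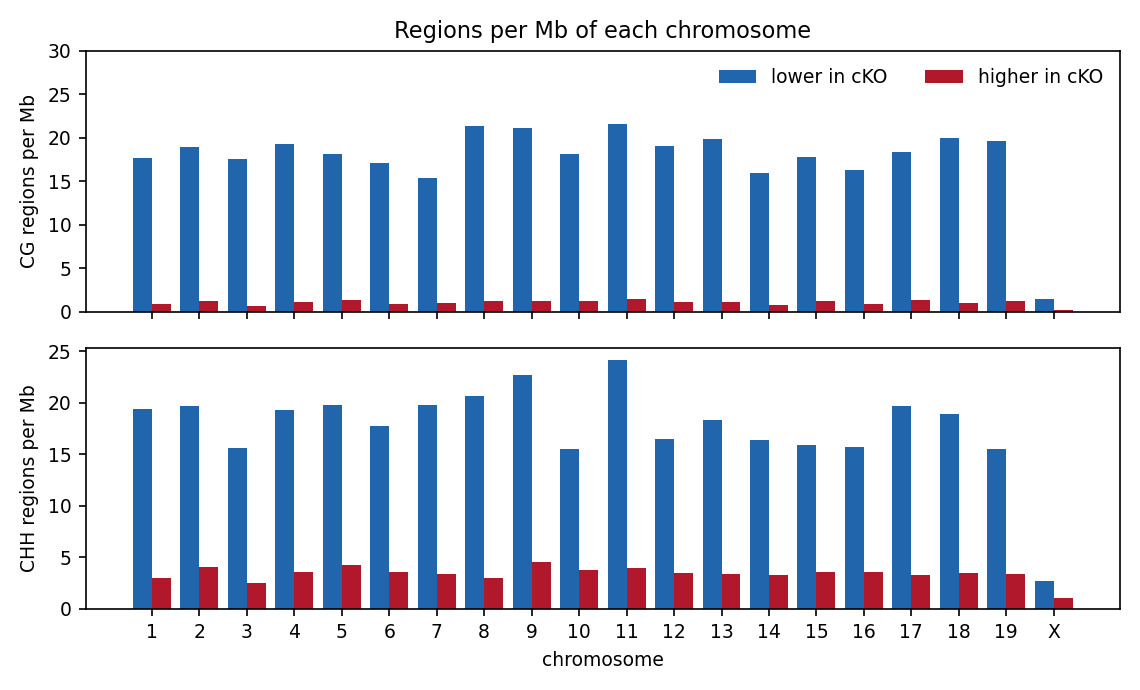
CG regions (top) and CHH regions (bottom) per Mb (vertical axes) on each autosome and the X, in blue for regions lower and in red for regions higher in cKO. On the X, CG regions lower in cKO stand at 1.46 per Mb, below all autosomes (15.4 to 21.6).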

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

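The filter on CHH differences above the mitochondrial median, the counting of 1 vote per gene and the adjustment over 46 tests were chosen after the results were seen. The direction of the CG and CHH regions and their placement in protein-coding genes held under each setting that left at least 20 regions, with 28.0% to 34.2% of CG losses, 85.5% to 93.2% of CG gains, 24.8% to 28.6% of CHH losses and 91.3% to 96.0% of CHH gains in such genes. The counts differ by construction, as each filter removes regions. At an absolute difference of at least 0.2, 1 CHH and 0 CHG regions were left, 95.5% of CG regions were lower in cKO, and the medians of CG regions lower and higher were -31.5 and 25.8 points. At 0.3, 25714 CG, 0 CHH and 0 CHG regions were left, 98.4% of CG regions were lower, and the medians were -35.1 and 33.0. At least 5 cytosines gave 94.2% lower and a median loss of -30.8 points in CG. At least 10 left 23145 CG and 389 CHG regions, with 92.9% lower and medians of -30.7 and 23.1 in CG. At least 100 bp left 29196 CG, 34854 CHH and 155 CHG regions, with 95.6% and 85.7% lower in CG and CHH, a median loss of -32.4 in CG, and medians of -4.70 and 5.64 in CHH. At least 200 bp left 12551, 6670 and 6, with 97.8% and 92.4% lower, medians of -34.5 and 24.8 in CG and of -5.20 and 7.53 in CHH. The stronger part by area statistic left 23562, 26804 and 310, with 93.4% and 86.0% lower, medians of -31.6 and 23.4 in CG and of -4.86 and 5.92 in CHH. Merging neighbours under 1 kb apart gave 93.6% and 82.7% lower and a median CHH loss of -4.44. Above the mitochondrial median, 10054 CHH regions were left, 71.9% lower, with medians of -6.72 and 6.91. On the X, the CG share lower was 93.0% at 0.2 and 96.1% at 0.3, against 95.5% and 98.4% on the autosomes. These differences no longer passed (Fisher exact p = 0.0789 and 0.0618), with odds ratios of 0.630 on 230 X regions and 0.411 on 129, against 0.406 on 278 in the full table. At 200 bp the X to autosome ratio of regions per Mb was 0.0495 in CG and 0.0847 in CHH. The cause was not tested. The number of list tests passed, 16 as reported, was 40 without matching on gene length, of which 14 were among the 16. It was 3 at 0.2 and 3 at 0.3 when adjusted over the 46 CG tests that kept regions, and 0 at both over all 92 tests, the adjustment used elsewhere. It was 8 at 10 cytosines. Above the mitochondrial median it was 5, with 1 of the 5 CHH calls and 4 of the 11 CG calls left; that filter leaves the CG regions as they are, so the CG calls ended through the joint adjustment alone, at the same ratios to random, and it is not counted for the CG lists. At 0.3 the activity-regulated genes and the area patterning genes had 0 members with a CG gain, where more than at random had one in the full table. Of the first 10 genes by count, ranking per 100 kb shared 0 for CG losses, 4 for CG gains, 0 for CHH losses and 1 for CHH gains, and at 0.3 the shared genes were 6 for CG losses and 4 for CG gains. No paired analysis was possible because the table holds group means and no values per library. For the same reason leaving out each replicate, a replicate block and a coverage minimum were not run. Counts of CpGs per chromosome, random regions matched on CpGs, promoters, exons and repeats were not run, as no genome sequence was used. With 0 repeated regions, counting repeats was not run. Of the calls for single lists and directions over these settings, 61 held, and 51 ended besides the 2 CG gain calls at 0.3 given above. Depth limits which regions could be called and is unknown.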

Other observations

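The tests and genes here were chosen after the results were seen. Losses in the 2 contexts lay near each other. Inside protein-coding genes, 44.8% of the CHH regions lower in cKO lay within 5 kb of a CG region lower in cKO (95% exact binomial interval 43.8% to 45.7%), against 2.91% of the CHH regions higher in cKO (2.55% to 3.31%). For the losses, random positions in protein-coding genes of the same chromosome gave at most 10.7% over 100 sets, and random positions in the same genes at most 31.5%. Outside these genes the shares were 41.2% and 9.47%. Of the CG gains 13.5% lay within 2 kb of an end of a protein-coding gene, where random regions had a mean of 6.11% and a maximum of 7.43% over 100 sets, and of the CG losses 7.15% did (mean 6.09%, maximum 6.51%). For CHH gains and losses the shares were 4.56% (mean 6.06%) and 5.34% (mean 6.11%). The random sets were not matched on lying in genes. Near Neurog2, a proneural transcription factor, a CHH region at 3.09 kb from the gene (chromosome 3, 127638729 to 127639448, 262 cytosines) was at 12.8% in control and 4.06% in cKO. In Mast4, a CHH region (chromosome 13, 102843977 to 102844467, 146 cytosines) was at 2.16% in control and 16.7% in cKO.

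Methylation fell in cKO at most listed CHH and CG regions, and also on mitochondrial DNA, which is usually taken to be unmethylated. There the control averaged 6.52% in CHH, 5.36% in CG and 9.55% in CHG and cKO 0.510%, 0.673% and 0.321%, so unconverted cytosines in the control libraries are a candidate source of losses. For the CHH losses, whose median control level of 5.52% lies near the mitochondrial one, unconverted cytosines stay open where conversion differed between regions. A failure at the mitochondrial level in all control DNA is argued against by the CHH regions higher in cKO. Control had a median of 1.69% there (quartiles 1.08% and 2.58%), though these regions are listed because control was the lower group. Of the CHH losses, 47.8% also had a control level below 5.43%, the lowest of a mitochondrial CHH region. For the CG losses, a failure at the mitochondrial level in all control DNA is argued against. Of them, 96.8% differed by more than 19.6 points, the largest mitochondrial difference. That share depends on the listing, as only 59 CG regions outside mitochondrial DNA differed by less than 10 points. Unconverted cytosines stay open for the CG losses too where conversion differed between regions. Noise spread evenly over genes is argued against because CHH losses inside genes lay near CG losses 4.46 times as often as random positions in genes did. Against random positions in the same genes the ratio was 1.45, so noise gathered in the same genes is not excluded by this. The random positions were not matched on depth, which is unknown. Uneven depth, an effect of the genotype on neuronal DNA and a change in the mix of cell types in the cortex stay open, as none was tested. The strongest CHH loss outside mitochondrial DNA (chromosome 1, 24612084 to 24613746, 9.95% to 0.620%) lies in a stretch known to hold a nuclear copy of mitochondrial DNA.

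For the CHH gains, an effect of the genotype and a change in the mix of neuron types both stay open, as neither was tested. Expression and histone methylation were not analysed here.

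Few regions lay on the X. The X to autosome ratio of CG regions per Mb was 0.0854, and the sex of the mice is not given in the labels. Weaker detection on the X that is alike for both directions is argued against by the odds of a lower against a higher region. On the X these odds were 0.406 times those on the autosomes in CG (95% interval by normal approximation 0.284 to 0.580), and 0.496 times in CHH (0.415 to 0.593). The intervals count regions as independent, which neighbours are not, and so may be too narrow. The CG odds ratio was 0.630 at an absolute difference of at least 0.2 (230 X regions) and 0.411 at 0.3 (129 X regions), where the difference from the autosomes no longer passed at either (Fisher exact p = 0.0789 and 0.0618). Lower depth on the X that weighs more on losses and an X that methylates differently in neurons stay open and may act together.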
